A study of Caenorhabditis elegans with 2 samples.

How the data were processed

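The samples were 2 immunoprecipitated libraries of whole young adult hermaphrodites with GFP-tagged F55B11.4, numbered as biological replicates 1 and 2 in the labels. They form 1 group, so the comparisons are between replicates and between peaks and the genome. Per the labels, chromatin was fragmented by sonication.

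For each of the genome builds ce10 and ce11 the authors deposited 4 peak lists: permissive calls of each replicate and of the pooled replicates, described in the deposited notes as peaks and background that serve as input for the IDR procedure, and the optimal IDR set derived from them. Per the deposited notes, each permissive list was made from the alignments of the immunoprecipitated library and of 1 control library, the same for both replicates, which was not analysed here. The aligner, the peak caller and the thresholds are not given in the sources used here. Each deposited call has a signal value, which is a score of peak strength set by the authors' peak caller on a scale that is not stated. The signal values served only to rank and describe calls within a list. The deposited lists also give the −log10 of a q-value for each call, as the authors' peak caller wrote it. In the optimal ce11 set these correspond to q from 0.0909 to 0.294, and 6 of the 48 peaks, all mitochondrial, had q under 0.1. The columns for a display score and a p-value hold fixed fill-in values and were not used. Calls had a median width of 490 bp in replicate 1 and 470 bp in replicate 2. Nearly all calls of a list had the same width, so positions were taken from summits. No read counts were analysed here, so intervals on shares cover the counting of peaks only.

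Analyses used the ce11 lists. The reference was the WBcel235 assembly, which is ce11, with the Ensembl release 115 annotation; symbols of mitochondrial genes came from the RefSeq gene table of the same assembly. All ce11 summits lay within the reference chromosomes. The ce10 lists were used only in alternatives that need no annotation, and no coordinate was converted between builds. The optimal ce10 set held 46 peaks, and 45 of the 48 ce11 peaks had a ce10 peak on the same chromosome with a signal value within 1%. A call of replicate 1 on ce10 spanned 400472 bp of chromosome X, while no ce11 call of that replicate was wider than 563 bp.

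Shares of summits near a feature (within 500 bp) were compared with 100000 random placements of the same number of summits, uniform within the chromosome of each, by two-sided permutation tests whose smallest p is 2e-05. Placement does not account for how well reads map or how open chromatin is. Fisher's exact test against permissive calls outside the optimal set was the alternative. This background joined the calls of both replicates, so a site called in both counts for each of them. Calls outside the optimal set are those that overlap none of its peaks. The classes of non-coding gene were tRNA, snRNA, snoRNA, rRNA, miRNA and piRNA, by annotated biotype, with Benjamini-Hochberg adjustment over the 6. Features were assigned in the order promoter (up to 500 bp upstream of a protein-coding 5′ end), 5′ untranslated region, coding exon, 3′ untranslated region, intron, non-coding gene and intergenic. The share on X was tested by an exact binomial test against its share of nuclear length. Gene lists were tested by two-sided Fisher's exact tests of genes with an optimal summit within 500 bp of a 5′ end against the protein-coding genes with a permissive call that near, 6868 in all. The lists were ribosomal proteins, mitochondrial ribosomal proteins, translation factors, proteasome, vacuolar ATPase, histones, collagens, vitellogenins, major sperm proteins, nuclear receptors, homeobox, heat shock, neuropeptides, F-box, chemoreceptors, C-type lectins, detoxification, muscle, intestine, hypodermis, neurons, germline and pharynx. Canonical 6-mers within 100 bp of the summits were compared with windows centred 1000 bp to either side. GC content was compared between the same windows by a sign-flip permutation test with 100000 resamples. Replicates were compared by the overlap, of at least 1 bp, of their 48 strongest calls and by Spearman correlation. Calls within 20 kb of F55B11.4 and unc-119 were counted against random windows, since a strain with an inserted transgene can carry extra copies of both. Peaks are not independent replicates, and p-values over peaks say nothing about variation between animals beyond the 2 replicates.

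The tests, lists and alternatives were fixed before the data were examined, as was the rule for names: the 25 strongest optimal peaks with the nearest protein-coding 5′ end and non-coding genes within 500 bp, up to 4 members of each list that passes, F55B11.4, unc-119 and the 5 6-mers with the smallest adjusted p. Mitochondrial peaks take 18 of the 25 places, so the strongest 5 were given in full and the rest summarised. Analyses of nuclear chromosomes only, of tRNA, snoRNA and snRNA genes as 1 class, of the wider call lists, and the alternatives for the snoRNA, snRNA, rRNA, miRNA and piRNA shares were chosen after seeing the data. Other settings, also fixed beforehand, covered the ce10 lists, the stronger part of the optimal set, each replicate alone, other distances, overlaps and backgrounds, and ranking by q. The tests were tested on simulated data. With 5 of 30 nuclear summits put at snoRNA genes the placement test passed in 100 of 100 runs, and with none it passed in 0 of 100. The other simulated summits were placed uniformly, as the test itself assumes. These runs therefore check the calculation and not the effect of uneven mapping or chromatin. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.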

Results

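Chromatin immunoprecipitation followed by sequencing was carried out on whole Caenorhabditis elegans hermaphrodites that carried F55B11.4 fused to GFP at its C terminus. The animals belonged to strain OP385, in which the tagged gene is an inserted transgene (wgIs385) in an unc-119 mutant background. They were collected as young adults 65 hours after synchronization as starved first-stage larvae, and the tagged protein was recovered with an antibody against GFP. The series has 1 group with 2 biological replicates, which the labels give as separate biosamples, and no control sample was analysed here. The deposited lists held 21050 permissive calls for replicate 1, 14257 for replicate 2 and 670 for the pooled reads of both, on genome build ce11. The number of reads behind each list was unknown. The authors' optimal set, derived by the irreproducible discovery rate (IDR) procedure, held 48 peaks. The rule by which it was selected is not given in the sources used here. All 48 were also the 48 strongest calls of the pooled list by the authors' signal value, a unitless score of peak strength that is compared only within a list.

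The strongest peaks lay on the mitochondrial genome. It held 18 of the 48 optimal peaks (37.5%, exact 95% interval 24.0 to 52.6), 17 of them among the 20 strongest. Of the 18 called intervals, 14 overlapped another. With summits within 500 bp counted 1 time, 10 of 40 peaks (25%) were mitochondrial, while the nuclear count stayed at 30. The other 30 peaks were on nuclear chromosomes. The strongest peak of all (chromosome M, 4375 to 5010, summit 4710) lay in the coding exon of CYTB, which encodes cytochrome b, with a signal value of 2171. It was followed by a peak in ND5 (summit 12453, 1567), one in COX3 (summit 6029, 994), one in ND1 (summit 2170, 791) and one in ND4 (summit 7286, 647). These genes encode subunits of respiratory complexes. The mitochondrial signal values had a median of 369, against 52.6 for the nuclear peaks. Of the 18 summits, 14 were inside a protein-coding gene. The other 4 lay in or next to the rRNA and tRNA genes. A tRNA gene was within 500 bp of 10 of the 18 (55.6%), against a mean of 68.2% for summits placed at random on the same genome (p = 0.364, two-sided permutation test). In the single-replicate lists, replicate 1 had 20 mitochondrial calls and replicate 2 had 21.

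**Figure D1:**
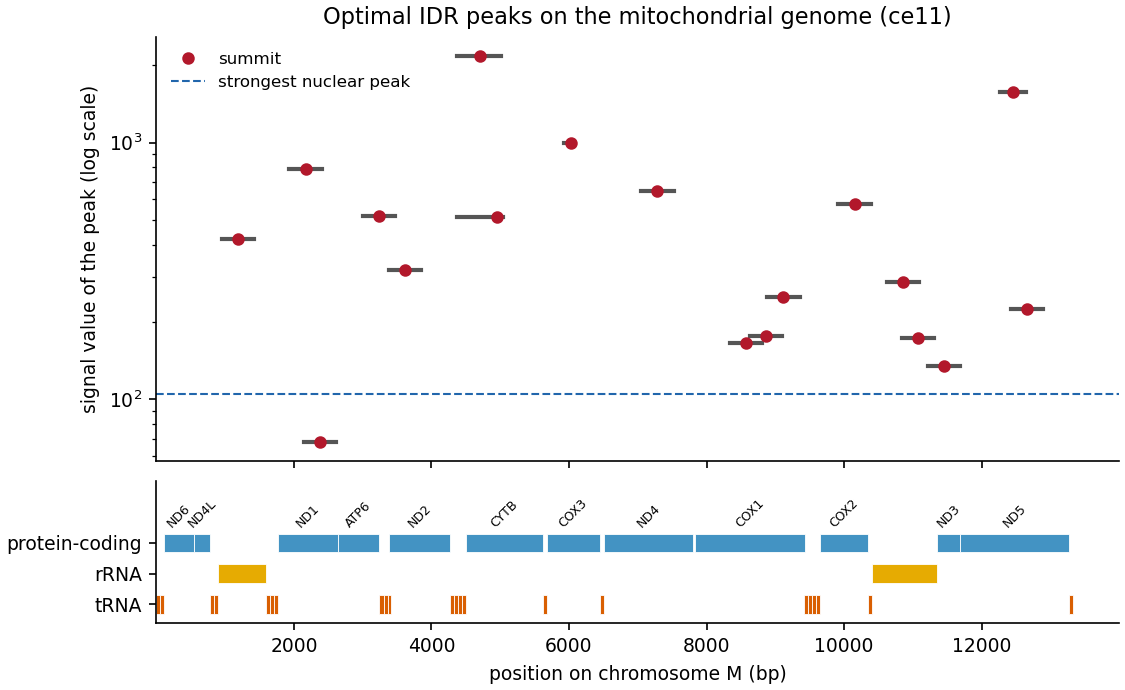
The upper panel shows the 18 mitochondrial optimal peaks by position (bp, horizontal axis) and signal value (log scale, vertical axis), with bars for the called interval and points for the summit; the lower panel shows the annotated genes. All but 1 peak, near the end of ND1 at a signal value of 68.0, lie above the dashed line at 105 that marks the strongest nuclear peak.

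On the nuclear chromosomes the peaks were concentrated at genes for small structural RNAs. A snoRNA gene, whose product guides the chemical modification of other RNAs, lay within 500 bp of 10 of the 48 optimal summits (20.8%, exact 95% interval 10.5 to 35.0). Random placement within the same chromosomes gave a mean of 0.243%. Among the 48 strongest calls of each replicate alone, the share was 12.5% in replicate 1 and 22.9% in replicate 2. Genes annotated as snRNA, the class of the spliceosomal and spliced leader RNAs, lay within 500 bp of 3 of the 48 (6.25%, interval 1.31 to 17.2), against 0.0751% at random. Both differences had an adjusted p of 6e-05 over 6 classes of non-coding gene (two-sided permutation test, Benjamini-Hochberg). The raw p was 2e-05 for each, the smallest that 100000 placements can give. For tRNA genes the share over all 48 peaks was 33.3%, against 25.9% at random (p = 0.119, adjusted p = 0.238, permutation test). That random share was high because 22 tRNA genes crowd the small mitochondrial genome. With nuclear chromosomes only, an alternative chosen after seeing the data, 6 of 30 summits lay near a tRNA gene (20%, interval 7.71 to 38.6, against 0.592% at random, p = 2e-05, permutation test). The snoRNA and snRNA shares were then 33.3% and 10%. A tRNA, snoRNA or snRNA gene was near 19 of the 30 nuclear summits (63.3%, interval 43.9 to 80.1), 57.6 times the random mean of 1.1% (p = 2e-05, permutation test). Against the permissive calls outside the optimal set, of which 2.53% were near such genes, Fisher's exact test gave p = 2.28e-23. That test treats calls as independent, although a site called in both replicates counts for each of them. Most calls of this background also ranked far below those behind the optimal peaks. No nuclear summit was near an rRNA, miRNA or piRNA gene. A count of 0 of 30 has an exact upper limit of 11.6%, which does not exclude the random shares of 0.0347%, 0.245% and 2.31%.

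**Figure D2:**
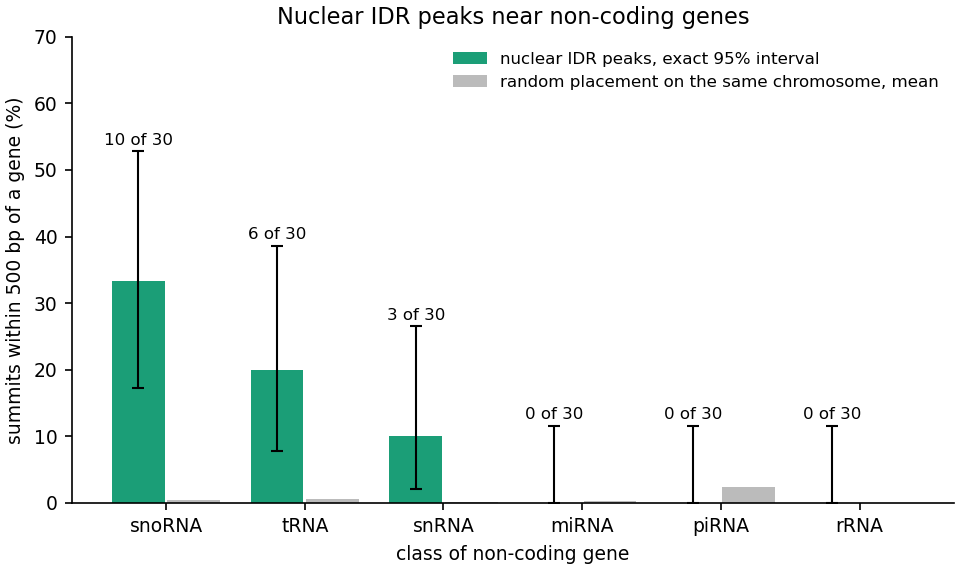
Share of the 30 nuclear optimal summits (green bars, %, with exact 95% intervals) within 500 bp of a gene of each non-coding class, beside the mean share of 100000 random placements (gray bars). The snoRNA, tRNA and snRNA shares of 33.3%, 20% and 10% stand above random means of 0.391%, 0.592% and 0.120%, and the other classes have no summit.

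The 4 strongest nuclear peaks were all at snoRNA genes. The strongest (chromosome V, 12303391 to 12303860, signal value 105) had its summit at 12303626, inside the snoRNA gene C51F7.4 (12303599 to 12303693), with a second snoRNA gene, C51F7.3, 82 bp away. Both lie in an intron of frm-7. The next peak (chromosome V, summit 8500538, 94.7) was 41 bp upstream of the snoRNA gene ZK994.7, in an intron of pxn-1. An intergenic peak on chromosome II (summit 11960776, 86.6) was 122 bp upstream of W03C9.9, and an intergenic peak on chromosome I (summit 8259552, 63.6) was 54 bp upstream of ZK265.10. The remaining 3 nuclear peaks among the 25 strongest were also at non-coding genes. On chromosome II (summit 14497074, 60.9) the summit was inside the non-coding RNA gene K10H10.14, 952 bp upstream of the nearest protein-coding 5′ end, that of dhs-8. On chromosome I (summit 4172398, 60.3) it was 83 bp beyond sls-2.4, a gene for the SL2 spliced leader RNA that is trans-spliced onto downstream mRNAs of operons. A second peak on chromosome I (summit 13463957, 60.1) lay 2 bp inside the 5′ end of rpr-1, the gene of the RNA component of RNase P, which trims tRNA precursors. This gene lies within an intron of ints-8.

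Among the 19 nuclear peaks at small RNA genes, 8 summits lay inside a protein-coding host gene and 11 did not. The peaks near tRNA genes, named after their values were seen, were at F15G9.t1 (in an intron of him-4), F47G6.t1 (in an intron of spe-15), C18A11.t2, R04D3.t2, C16B8.t1 and C02B4.t2 (in an intron of nhr-17). Of these 6, 5 were on the X chromosome. Every 32-base word of these 6 tRNA genes also occurred elsewhere in the genome, so reads inside them could come from other copies. The other 2 snRNA-class peaks were at R07E5.16 and F54D8.7 on chromosome III, which were repeated over their whole length in the same way. Of the 10 snoRNA peaks, 8 had no repeated word in the snoRNA gene. Relative to the nearest small RNA gene, 10 summits lay upstream of the 5′ end, 6 inside and 3 downstream, with a median position 10 bp upstream of the 5′ end.

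**Figure D3:**
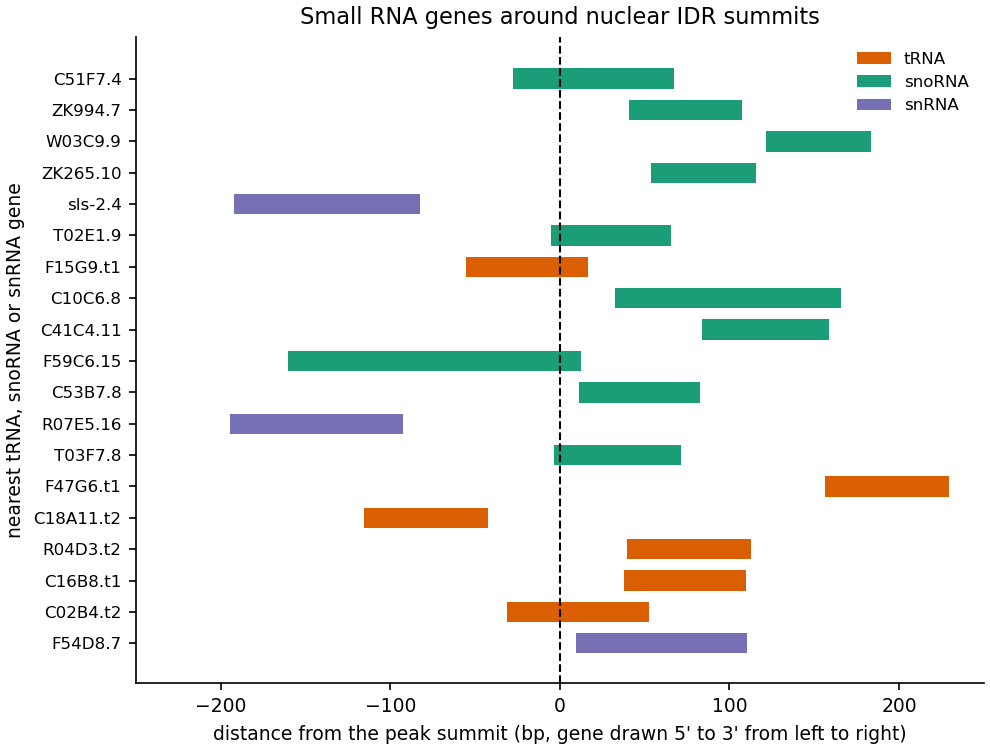
Each bar is the nearest tRNA, snoRNA or snRNA gene of 1 of the 19 nuclear peaks, drawn 5′ to 3′ from left to right by its distance in bp from the peak summit (dashed line at 0). The genes lie close to the summit on either side, with 10 summits upstream, 6 inside and 3 downstream of the gene.

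The other 11 nuclear peaks, 2 of which are the K10H10.14 and rpr-1 peaks above, included summits in coding exons of hsp-1 (chromosome IV, 17279494, signal value 47.2) and hsp-110 (chromosome III, 8444890, 53.1), both genes of Hsp70-family chaperones. Others were in the coding exons of the homeobox gene ceh-9 (chromosome I, 565829, 45.6) and of T26H5.8, in the 5′ untranslated region of kin-14 (chromosome I, 7079467, 50.7), and 106 bp upstream of Y17D7C.2. These were chosen after their values were seen. For 2 of the 11, on chromosomes V and III, over 50% of the 32-base words in the window around the summit occurred more than 1 time in the genome (85.9% and 59.4%), so reads there could come from other copies.

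Replicates were compared through their strongest calls. Of the 48 strongest calls of replicate 1, 28 (58.3%) overlapped 1 of the 48 strongest of replicate 2, against 36.3% for random placement (p = 2e-05, two-sided permutation test). Mitochondrial calls raised both values. Ranked by q instead, 13 of 48 (27.1%) overlapped, against 14.5% at random. Among the 96 strongest calls the share was 36.5% against 18.2%, and among the 480 strongest 14.8% against 4.03% (p = 2e-05 in each, permutation test). The replicates were called against the same control library, so part of any overlap can come from that control. Among the 48 strongest nuclear calls of each replicate, 13 (27.1%) overlapped, against 0.0486% at random (p = 2e-05, permutation test). All 13 overlapped an optimal peak, so they repeat peaks counted above. A tRNA, snoRNA or snRNA gene was near 9 of these 13, and near 14 of the other 35 calls of replicate 1 (40%). Such genes were near 23 of the 48 strongest nuclear calls of replicate 1 (47.9%) and 28 of those of replicate 2 (58.3%), each above random placement (p = 2e-05 in each, permutation test). Of these calls, 17 in replicate 1 and 22 in replicate 2 overlapped an optimal peak, so the shares are not fully separate from the optimal set. The optimal set was derived from the lists of these replicates, so overlap with both may be built in. All 30 nuclear optimal peaks overlapped a call in both replicates. Their median rank was 51.5 in replicate 1 and 39 in replicate 2, and 3 ranked beyond 1000 in replicate 1. Over all calls, 24.1% of those of replicate 1 overlapped a call of replicate 2, against 12.8% at random, and the Spearman correlation of signal values across the 5076 overlapping calls was 0.124 (p = 2e-05, 100000 permuted pairings). Among the strongest 1000 calls of replicate 1, 43.6% overlapped a call of replicate 2, against 14.2% at random, and the correlation was 0.343. These correlations are across calls, which are not independent replicates.

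**Figure D4:**
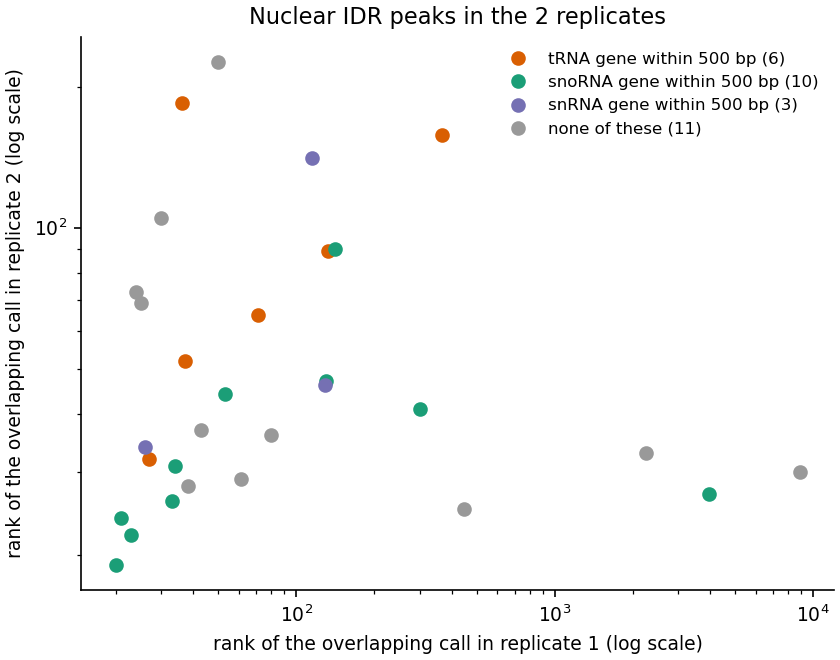
Rank by signal value of the call that overlaps each of the 30 nuclear optimal peaks in replicate 1 (horizontal) and replicate 2 (vertical), both on log scales and counted with the mitochondrial calls, coloured by the class of small RNA gene within 500 bp. Ranks in replicate 2 stay within 226, while 3 peaks lie beyond rank 1000 in replicate 1, the farthest at 8856.

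The share of optimal peaks near protein-coding 5′ ends did not pass the test against random placement at any distance tried. The annotated 5′ end of a protein-coding transcript lay within 500 bp of 14 of the 48 summits (29.2%, exact 95% interval 17.0 to 44.1), against 41.1% at random (p = 0.0760, two-sided permutation test). The direction turned at 1000 bp, with 34 of 48 (70.8% against 60.1%, p = 0.109, permutation test), and against the permissive calls outside the optimal set (25.4%, p = 0.512, Fisher's exact test). On the nuclear chromosomes the count was 4 of 30 (13.3% against 22.9%, p = 0.298, permutation test). This nuclear share was also below that of the nuclear permissive calls (25.4%, p = 0.146, Fisher's exact test). The turn against permissive calls thus appeared only with the mitochondrial peaks included. The wider nuclear lists, examined after seeing the data, were slightly above random: 27.7% against 22.8% for the 618 pooled calls that overlap no optimal peak (p = 0.0061), 25.2% against 23.1% in replicate 1 and 25.7% against 23.2% in replicate 2 (p = 2e-05 in each, permutation tests). Many worm mRNAs are trans-spliced, so an annotated 5′ end is not always where transcription starts. By annotated feature, 9 of the 48 summits lay in promoters, 1 in a 5′ untranslated region, 15 in coding exons, 0 in 3′ untranslated regions, 9 in introns, 4 in non-coding genes and 10 between genes. None of the 7 shares passed the permutation test against random placement, with an adjusted p of 1 for each and 0 of 7 at an unadjusted p under 0.05. These counts include the mitochondrial peaks. On the nuclear chromosomes 2 of 30 summits lay in promoters, 5 in coding exons, 9 in introns and 3 in non-coding genes, and again no share passed. Introns precede non-coding genes in the order, so a summit in an intronic small RNA gene, such as C51F7.4, counts as intron. The X chromosome held 6 of the 30 nuclear peaks (20%, exact 95% interval 7.71 to 38.6), against 17.7% of nuclear sequence (p = 0.640, two-sided exact binomial test). Among the strongest calls it held 6 of 28 nuclear calls in replicate 1 alone (21.4%) and 3 of 27 in replicate 2 alone (11.1%), and in the stronger part of the optimal set 0 of 6 nuclear peaks; none of these passed the threshold.

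Only 13 protein-coding genes had an optimal summit within 500 bp of an annotated 5′ end, 8 of them mitochondrial. The 5 nuclear genes were spe-15, kin-14, chst-1, C41C4.9 and Y17D7C.2. The peak at spe-15 was also near a tRNA gene, and the peak shared by chst-1 and C41C4.9 was near the snoRNA gene C41C4.11. None of the 13 belonged to any of the 23 gene lists, among them ribosomal proteins, translation factors, histones, collagens, nuclear receptors, homeobox and heat shock genes, and markers of muscle, intestine, hypodermis, neurons, germline and pharynx. Thus 0 of 23 lists passed Fisher's exact test, with 0 at an unadjusted p under 0.05. The 8 mitochondrial genes could belong to no list, so this rests on 5 genes and leaves an enrichment of any list open. The hsp-1, hsp-110 and ceh-9 summits were farther than 500 bp from a 5′ end of these genes. At 1000 bp, hsp-1, ceh-9 and the chemoreceptor gene sre-23 entered their lists, with an unadjusted p of 0.0360 for heat shock genes (adjusted p = 0.828, Fisher's exact test) and 0 of 23 lists passing.

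Sequence around the summits was richer in G and C than its surroundings. Windows within 100 bp of the 48 summits had 39.1% ± 10.4 GC (SD across peaks), against 31.7% ± 8.38 in windows centred 1000 bp to either side. The difference was 7.34 ± 7.92 percentage points (SD across peaks), higher in 41 of 48 peaks (p = 1e-05, sign-flip permutation test, the smallest it can give). Flanking windows that lay on other peaks were not excluded. On the small mitochondrial genome some did, so the same sequence counts on both sides there. With nuclear chromosomes only, the values were 45.9% and 36.6%, a difference of 9.32 ± 8.25 points, higher in 27 of 30 peaks (p = 2e-05, sign-flip permutation test). Nuclear peaks near small RNA genes and the other nuclear peaks showed like differences, of 9.02 and 9.84 points over 19 and 11 peaks. No 6-mer passed Fisher's exact test among 2080 tested with Benjamini-Hochberg adjustment, with 121 at an unadjusted p under 0.05 and a smallest adjusted p of 0.458. The 5 with the smallest adjusted p were AGAAAC, present in 1 of 48 peak windows and 22 of 96 flanking windows, CAAGGC (8 and 1), GCACAC (9 and 2), AGGCGG (6 and 0) and CGAGCG (6 and 0). These counts include the mitochondrial windows that lay on other peaks. With nuclear chromosomes only, no 6-mer passed either (smallest adjusted p = 0.545, Fisher's exact test). In simulated data with 48 windows, a 6-mer planted in 10 windows was called in 2 of 20 runs, 1 planted in 16 windows in 14 of 20, and 1 planted in 25 windows in 19 of 20. The simulated windows came from random nuclear positions, while 18 of the 48 real ones are mitochondrial, so the rates may differ for the real set.

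No count of calls around the gene that was tagged passed the test. If the control library carries the same extra copies, these could raise no excess of calls, so the counts do not measure copy number. Within 20 kb of F55B11.4 (chromosome IV, 14429572 to 14430920, minus strand), replicate 1 had 13 permissive calls against a mean of 8.67 in random windows of the same length (p = 0.254, two-sided permutation test) and replicate 2 had 7 against 5.88 (p = 0.753). Around unc-119 (chromosome III, 10902641 to 10908935, plus strand) the counts were 12 against 9.71 in replicate 1 (p = 0.583) and 10 against 6.59 in replicate 2 (p = 0.307, permutation test). Neither window held an optimal peak. Counted among the 1000 strongest calls, F55B11.4 had 2 in each replicate, against 0.413 and 0.415 at random (p = 0.148 and 0.152, permutation test). In the same count unc-119 had 3 in replicate 1 against 0.462 at random (p = 0.0343, permutation test) and 0 in replicate 2.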

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

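Of 131 alternative values for 27 results, 27 changed direction (19 of them) or side of the threshold, or were counts of peaks that moved by over 1.5 times. Another 27 kept both but moved by over 1.5 times. Among these were the replicate overlap (36.5% and 14.8% for the 96 and 480 strongest calls, 27.1% ranked by q or on nuclear chromosomes), the correlation of the strongest 1000 calls (0.343), the shares within 200 bp of a 5′ end (8.33%) or a tRNA gene (16.7%), the nuclear share near a 5′ end (13.3%) and the snoRNA share of replicate 1 alone (12.5%). The snoRNA and snRNA shares kept their direction and had an unadjusted p under 0.05 in every alternative run on them; the largest, for snRNA in the stronger part (1 of 24, p = 0.0182, permutation test), was not adjusted over the 6 classes. The alternatives named here as nuclear only, those for rRNA and piRNA genes and those for the combined class of tRNA, snoRNA and snRNA genes were chosen after seeing the data. The cause was not tested unless stated.

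The optimal set fell to 24 peaks in its stronger part and to 30 on nuclear chromosomes, both by construction. The stronger part has 18 mitochondrial peaks, and there the combined share was 62.5% but no longer past the threshold (p = 0.273, permutation test), the tRNA share of 41.7% was below random, and the X share was 0%. The tRNA share, which missed the threshold over all chromosomes, passed it with nuclear chromosomes only (20%), at 1000 bp (50%) and against permissive calls (33.3%). Few permissive calls are mitochondrial, but the nuclear share also passed against them (20% against 1.57%, p = 6.76e-06, Fisher's exact test). Near 5′ ends the share was 70.8% at 1000 bp, above random, and 29.2% stood above the permissive calls, and both missed the threshold. On nuclear chromosomes the share stayed below the permissive calls (13.3% against 25.4%, p = 0.146, Fisher's exact test).

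The remaining changes of direction were in differences that missed the threshold before and after. Each replicate alone gave an rRNA share of 10.4%, and nuclear chromosomes 0% and a distance of 1000 bp 14.6%. Against permissive calls, few of which are mitochondrial, the rRNA share of 10.4% passed the threshold (0.00853%, p = 2.11e-13, Fisher's exact test). The piRNA share at 1000 bp was 2.08%. Features in the stronger part were 0% for 5′ untranslated regions and 8.33% for introns. Ranges over the replicates taken alone were 20.8% to 25% for promoters, 35.4% for coding exons, 0% to 4.17% for 3′ untranslated regions, 14.6% to 18.8% between genes and 11.1% to 21.4% for X. Replicate 2 had 3 calls within 10 kb of F55B11.4. Among the 1000 strongest calls unc-119 had 3 in replicate 1, now past the threshold, and 0 in replicate 2. No paired analysis was possible because the series has 1 group.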

Other observations

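The wider call lists, examined after the optimal peaks were seen, held calls near the same classes of gene, and calls near protein-coding 5′ ends at slightly above the random share (27.7% against 22.8% in the pooled calls outside the optimal set, p = 0.0061, permutation test). Among nuclear pooled calls that overlap no optimal peak, 112 of 618 (18.1%, exact 95% interval 15.2 to 21.4) lay within 500 bp of a tRNA, snoRNA or snRNA gene, against 1.11% at random (p = 2e-05, permutation test). By rank of all nuclear pooled calls, the share was 63.3% for ranks 1 to 30, which are the nuclear optimal peaks themselves. Beyond these it was 47.1% for ranks 31 to 100, 25% for 101 to 300 and 8.86% for 301 to 650. In replicate 1 it was 50% for ranks 1 to 30 and 1.67% beyond rank 10000, and in replicate 2 it was 60% and 1.79%. A call of each replicate lay within 500 bp of 180 of 612 nuclear tRNA genes (29.4%), 81 of 346 snoRNA genes (23.4%), 20 of 129 snRNA genes (15.5%), 29 of 261 miRNA genes (11.1%) and 344 of 15363 piRNA genes (2.24%). The 2 calls need not overlap, and no random share was set beside these counts. Near miRNA genes lay 9 of the 618 nuclear pooled calls that overlap no optimal peak (1.46% against 0.260% at random, p = 0.00012, permutation test), although no optimal peak did. Permissive calls were slightly rarer near piRNA genes than random placement gives, at 3.96% against 4.51% in replicate 1 and 3.88% against 4.62% in replicate 2.

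The tests of GC content, repeated words in the windows and the X chromosome were written before their results were seen, and those of repeated genes, summit position and mitochondrial coverage after. For the concentration of nuclear peaks at small RNA genes, random positions matched to the peaks in GC content within 2 percentage points lay near such genes in 1.64% of cases, against 63.3% of the peaks (p = 2e-05, permutation test), which argues against GC content as the whole cause. In 0 of the 19 windows did over 50% of 32-base words recur in the genome, but a wholly repeated gene could fill that much of only 3 windows, so this decides nothing. Within the genes themselves, over 50% of words recurred at 1 of the 10 snoRNA peaks (exact 95% interval 0.253 to 44.5), which argues against shared reads there, and at 8 of the 9 tRNA and snRNA peaks (51.8 to 99.7), where reads shared between copies may contribute. Of the 19 summits, 10 lay upstream of the gene and 9 inside or downstream (p = 1, exact binomial test), and of the 13 outside the gene 10 were upstream and 3 downstream (p = 0.0923, exact binomial test), so neither test separated upstream summits from the rest. It stays open whether the tagged protein binds these genes or whether short, highly transcribed genes may be recovered in such experiments whatever protein is tagged: an untagged strain or another tagged factor was not analysed here, the 1 control shared by both replicates is part of every call, and no biological explanation was tested.

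For the mitochondrial peaks, a general excess of mitochondrial fragments in the immunoprecipitated libraries over the control could raise signal along the whole genome. The peaks covered 46.6% of it (6429 of 13794 bp), which is between the values set for such an excess and for localized binding. The value set for an excess could not be reached by 18 intervals of at most 670 bp, so this coverage decides nothing. An excess and localized binding cannot be told apart without read coverage. A difference in mitochondrial content between the libraries and their control was not tested, and no biological explanation was tested.

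The X chromosome held 150 of the 652 nuclear pooled calls (23.01%), against 17.7% of nuclear length (p = 0.000565, exact binomial test). It also holds 276 of the 612 nuclear tRNA genes (45.1%). Without the calls within 500 bp of a tRNA gene the share was 18.3% (105 of 573, exact 95% interval 15.2 to 21.7, p = 0.662), so tRNA genes may account for the excess in the pooled list. They do not account for that among permissive calls of replicate 1, where the share without such calls was 21.02% (p = 5.56e-35, exact binomial test); in replicate 2 the share of all nuclear calls was 18.3% (p = 0.0432). The difference between replicates was not tested.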
